A study of Mus musculus with 8 samples.

How the data were processed

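Total RNA from isolated mouse glomeruli was labelled as biotinylated cRNA and hybridised to Affymetrix arrays, 1 array per sample, per the labels' protocols. The 8 arrays form 3 groups by their labels: 2 control arrays, 3 arrays of Tln1 Pod-rtTA TetO-Cre mice given vehicle (Tln1 vehicle) and 3 arrays of such mice given valproic acid (Tln1 VPA). The number of arrays limits the precision of every value.

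The deposited values are log2 expression values made with RMA, per the submitters' processing notes, which also name limma. Versions, annotation and genome build are not given in the sources used here. Each array had 41345 probe sets, with values between 1.49 and 13.9. This range marks a log2 scale, the values are not centred per gene, and higher values stand for more RNA. No scanner values were used here, so it stays unknown which arrays were normalised together. Of the probe sets, 23521 had 1 gene symbol, 1814 had several and 16010 had none in the platform annotation used here. Entrez identifiers matched the gene table for 23328 probe sets and changed 0 symbols. Of the probe sets with 1 symbol, the one with the highest mean over all arrays was kept per gene, which left 22180 genes. Probe sets with several symbols or none were tested without naming a gene. The files gave no coordinates that were used here.

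All 3 comparisons came from 1 limma fit (lmFit and eBayes, group as the only term) in R 4.3.3 with limma 3.58.1, two-sided. Adjusted p values are Benjamini-Hochberg values over all genes, and a gene was called at an adjusted p below 0.05. Gene lists were tested with limma's camera with a preset correlation of 0.01 between genes, adjusted over the lists. The same lists were run with an estimated correlation and with fry, which tests whether a list's genes move on balance one way without comparing them with other genes. Of 23 lists, 21 were tested: the erythroid list had fewer than 5 measured genes, and the sex-linked list served only to compare the arrays. In all, 483 of the 533 list genes were measured. List symbols absent from the arrays were looked up through synonyms. The measured kidney injury list holds Olfr48, an olfactory receptor gene by its symbol, which is included in the values of that list. A list's change is the mean log2 change of its measured members. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

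The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. By that rule the text names Tln1, Egr1, Hdac1 and Hdac2. It also names, as no gene was called, the 4 genes per direction with the smallest p whose arrays do not overlap between the groups and whose mean in the higher group lies above the median gene mean of 4.92. From each called list, and from the podocyte markers, it names members among the 4 with the smallest p. Genes outside this rule are said to have been chosen after their values were seen. Of the genes named by the rule, Ccl20, Top2a, Prc1, Rrm2, Cd14, Cd44, Timp1 and Slitrk1 had low values. Their means over all arrays did not exceed the median gene mean.

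The fits were tested on simulated data with the spread of the real arrays. For Tln1 vehicle against control, 36% of 100 genes changed by 1 log2 unit and 84% of 100 genes changed by 2 units were called. For Tln1 VPA against Tln1 vehicle these shares were 46% and 92%, and for Tln1 VPA against control 38% and 78%. With the array set as a block, 94%, 95% and 90% of the genes changed by 1 unit were called in the 3 comparisons, beside 14, 7 and 11 unchanged genes. These shares hold for 100 changed genes of each size and a set effect that is the same in all groups, as simulated. A simulated list shift of 0.50 was called in each comparison, beside 2, 0 and 1 unshifted lists. Smaller shifts, as most of the observed ones were, were not simulated. Other splits of the real Tln1 arrays, given in the closing section, called 3 to 16 lists. The simulated counts therefore do not show how often lists are called falsely in these arrays.

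Clustering of the arrays by correlation gave 2 array sets, described with the results, and every comparison was therefore also fitted with the array set as a block. That fit, the first set alone, the mean of the Y-linked genes Kdm5d, Uty and Eif2s3y as a covariate, and both terms together were added after the data had been seen. Same-numbered Tln1 vehicle and Tln1 VPA arrays deviated together from their group means (r = 0.570, 0.609 and 0.787 across genes), which pairs them by the rule used here. The labels do not state a pairing, and other pairs within the first set gave 0.510 and 0.515, so most of this follows the array sets. Control and Tln1 vehicle share only 2 numbers (r = 0.609 and -0.591) and were not taken as paired. The alternatives set beforehand were the mean of a gene's probe sets, every probe set as its own row, only genes above the median level, centring, quantile normalisation, trended and robust eBayes, array weights, only the 2 groups compared, an added minimum change of 1 log2 unit, the replicate number as a block, the mean of the proximal tubule markers as a covariate, and each array left out in turn.

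The planned share of called genes whose change was opposite under valproic acid had no value, since no gene was called. In its place the share among genes with an unadjusted p below 0.01 was computed, a choice made after the data had been seen. Both comparisons use the same vehicle arrays. This share and the correlation of the changes are therefore given beside 100 simulations of unchanged groups and 100 without a drug effect. Noise in these simulations was drawn independently for each gene. For the explanations weighed in the closing section, a value was first judged against 2 standard errors and then, after the results had been seen, against its 95% interval. The change left the test of the cell cycle genes against the macrophage markers open where it had counted against the explanation.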

Results

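Gene expression was measured in glomeruli isolated from kidneys of 13-week-old mice. Podocytes are the epithelial cells of the filtration barrier. Per its name, the line Tln1 Pod-rtTA TetO-Cre carries a Cre recombinase that is driven in podocytes by doxycycline and acts on Tln1. That gene encodes talin 1, which ties integrins to the actin cytoskeleton. Doxycycline was given for 3 weeks from an age of 8 weeks to all groups. Mice of the line then received vehicle (3 arrays) or valproic acid, an inhibitor of histone deacetylases (3 arrays), for 2 weeks, and 2 arrays came from control mice. The series text speaks of control and proteinuric mice. The labels do not say that the arrays stand for separate animals, so p values of single genes measure only the spread between these samples, which may be technical. Camera p values with the preset correlation set a list's genes against other genes and treat its members as nearly independent. A very small one is therefore not strong evidence from these few arrays. For cell cycle genes in Tln1 VPA against Tln1 vehicle, camera's adjusted p went from 7.77e-28 to 0.0602 with an estimated correlation.

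The median log2 value of all probe sets was 4.23 and 4.14 in control 1 and 2, 4.26, 4.26 and 4.15 in Tln1 vehicle 1 to 3, and 4.26, 4.29 and 4.14 in Tln1 VPA 1 to 3. The arrays fell into 2 sets that do not follow the groups: a first set of 5 (control 1, Tln1 vehicle 1 and 2, Tln1 VPA 1 and 2) and a second set of 3 (control 2, Tln1 vehicle 3, Tln1 VPA 3). Correlations across genes were 0.990 to 0.995 within a set and 0.966 to 0.979 across the sets, and the axis that parted the sets held 65.0% of the variance. Podocyte markers averaged 7.44 to 7.90 in the first set and 8.29 to 8.80 in the second, and proximal tubule markers 11.20 to 11.70 and 10.01 to 10.58. The change of each called list is therefore given over all arrays and within the first and the second set (sets), where the second set has 1 array per group and the first has 1 control array.

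The arrays also differed in sex-linked transcripts. The Y-linked gene Eif2s3y stood at 6.46, 7.71, 5.43 and 6.51 in the first-set Tln1 arrays (vehicle 1 and 2, VPA 1 and 2), at 3.80 in control 1, and at 2.69 to 2.91 in the second set. Xist, which is transcribed from the inactive X chromosome of females, was between 7.38 and 10.94 in all 8 arrays. Within the first set, the Y-linked signal thus moved with the Tln1 groups.

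**Figure D1:**
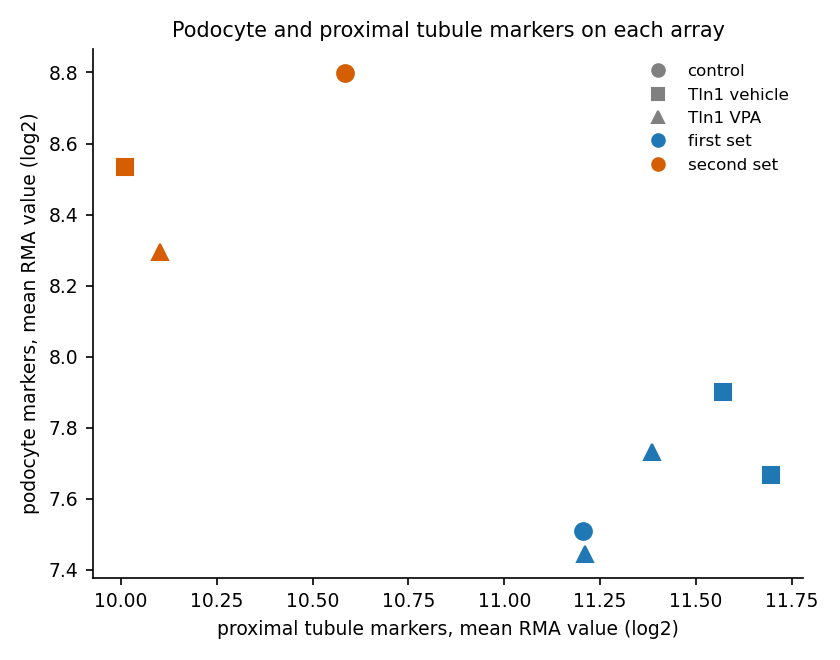
Mean RMA value (log2) of the podocyte markers (vertical axis) against that of the proximal tubule markers (horizontal axis), 1 point per array, with shape for the group and colour for the array set. The second-set arrays lie at 8.29 or above for podocyte markers and at 10.58 or below for tubule markers, and all first-set arrays lie on the other side of both.

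The first comparison, Tln1 vehicle (n = 3) against control (n = 2), addressed what differs in glomeruli after the podocyte change. The labels do not say whether control mice received vehicle, so the genetic change and 2 weeks of vehicle may both differ in every comparison with control. The mix of male and female RNA may differ too, since the Y-linked signal moved with the Tln1 groups in the first set. Tln1 itself averaged 8.80 ± 0.23 (SD) in control and 8.83 ± 0.20 in Tln1 vehicle arrays. Where its probe set lies relative to the deleted part is not known here, and podocytes are a part of the isolate, so this value checks no label. Egr1, an immediate early transcription factor, had the smallest p of all genes, at 6.20 ± 0.34 in control, 8.01 ± 0.17 in Tln1 vehicle and 6.88 ± 0.32 in Tln1 VPA arrays. Its change was 1.81 (SE 0.23), with 1.95 in the first and 1.77 in the second set, but it did not pass over all genes (adjusted p = 1.00). Markers of mesangial and vascular smooth muscle cells rose together, from a mean level of 6.72 ± 0.08 to 7.11 ± 0.18, with every Tln1 vehicle array above both control arrays, a call not kept with an estimated correlation (adjusted p = 0.0687).

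Of the 17 measured mesangial and smooth muscle markers, 14 were higher and 3 lower (mean change 0.38, camera adjusted p = 1.30e-06, adjusted p = 0.0687 with an estimated correlation, 3.75e-10 to 0.377 over 18 alternatives). The call held without any single array. The mean was 0.25 in the first set, where the list was not called when tested alone, and 0.60 in the second. No marker passed over all genes and 3 passed adjusted over the list alone. These were Itga8, the integrin chain of mesangial cells (1.17, SE 0.26), Des, the intermediate filament desmin, which injured podocytes also make (1.06, SE 0.26), and Pdgfrb, the receptor for platelet-derived growth factor on mesangial cells and pericytes (0.74, SE 0.19).

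The other calls in this comparison were each lost when a single array was left out. Immediate early genes rose (mean 0.39, sets 0.38 and 0.66, 18 of 24 higher, adjusted p = 2.06e-05, adjusted p = 0.929 with an estimated correlation, 1.58e-16 to 0.966 over the alternatives). Junb was at 0.84 (SE 0.28, 0.53 without Tln1 vehicle 3) and Zfp36 at 0.47 (SE 0.21, 0.24 without control 1), and Egr1 alone passed adjusted over the list alone. The call was lost without control 1 (mean 0.12) and without Tln1 vehicle 3 (0.11), and the mean was 0.65 without control 2. Cholesterol synthesis genes fell (mean -0.25, sets -0.37 and -0.38, 15 of 16 lower, adjusted p = 2.06e-05, adjusted p = 0.929 with an estimated correlation, 1.39e-08 to 0.965 over the alternatives). Fdps was at -0.70 (SE 0.21, -0.31 without control 1 and -1.09 without control 2), Dhcr7 at -0.32 (SE 0.19, -0.06 without control 1, -0.59 without control 2 and -0.21 without Tln1 vehicle 3) and Sc5d at -0.23 (SE 0.14, -0.11 without control 1 and -0.35 without control 2). Their call was lost without control 1 (mean 0.10) and without Tln1 vehicle 3 (-0.01), and the mean was -0.61 without control 2 and -0.38 without Tln1 vehicle 2. Cell cycle genes rose (mean 0.20, 21 of 25 higher, adjusted p = 0.00297, adjusted p = 0.929 with an estimated correlation, 3.04e-04 to 0.965 over the alternatives). The proliferation marker Mki67 was at 0.70 (SE 0.24) and Rrm2, a subunit of ribonucleotide reductase, at 0.63 (SE 0.31). Cell cycle genes were not called without control 1, though their mean was larger (0.28), or with the Y-linked covariate (0.04), and their mean was 0.11 without control 2 and 0.17 and 0.16 in the sets. Genes of NF-kB signalling and cytokines rose (mean 0.15, sets 0.06 and 0.32, 19 of 26 higher, adjusted p = 0.00838, adjusted p = 0.929 with an estimated correlation, 2.40e-06 to 0.965 over the alternatives). Tnfaip3, which restrains this pathway, was at 0.39 (SE 0.15, 0.25 without control 2) and the cytokine Il34 at 0.67 (SE 0.33, 0.18 without control 1 and 1.16 without control 2). Without control 1 (a larger mean of 0.18) or Tln1 vehicle 3 (0.08), and in the first set alone (0.06), they were not called. Glomerular endothelial markers rose (mean 0.14, 21 of 28 higher, adjusted p = 0.00828, adjusted p = 0.929 with an estimated correlation, 1.57e-13 to 0.965 over the alternatives). Their mean was -0.25 in the first set and 0.75 in the second, and the call was lost without control 2 (-0.02) and without Tln1 vehicle 3 (-0.09). Without control 1 and without Tln1 vehicle 2 the mean was 0.29 and 0.35. Ehd3, enriched in glomerular endothelium, was at 0.74 (SE 0.28, 0.40 without control 2), and Kdr, the main receptor for vascular endothelial growth factor, at 0.56 (SE 0.31, 1.04 without control 1 and 0.08 without control 2) over all arrays and -0.10 in the first set.

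Podocyte markers showed no steady shift, and with the Y-linked covariate they were called higher (0.36). Of 33 measured, 23 were lower and 10 higher (mean -0.12, adjusted p = 0.108, adjusted p = 0.929 with an estimated correlation, 2.55e-17 to 0.972 over the alternatives), with a mean of 0.27 in the first set and -0.26 in the second. Without control 1 and without Tln1 vehicle 3 the list was called lower (-0.76 and -0.37), without control 2 it was called higher (0.52), and it lay at -0.05 without Tln1 vehicle 1 and at 0.06 without Tln1 vehicle 2. Sema3g, a semaphorin secreted by podocytes, was at -1.01 (SE 0.43, -1.56 without control 1 and -0.46 without control 2), Foxc2, a podocyte transcription factor, at -0.58 (SE 0.59, -1.53 without control 1, 0.37 without control 2, -0.31 without Tln1 vehicle 2 and -0.95 without Tln1 vehicle 3) and Enpep, aminopeptidase A, at -0.25 (SE 0.28, -0.73 without control 1, 0.22 without control 2 and -0.15 without Tln1 vehicle 2), and the last 2 were at 0.00 and 0.10 in the first set.

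Among single genes, Cyp4a12b, a cytochrome P450 (1.35, SE 0.23), Adamts1, a secreted metalloprotease (0.64, SE 0.13), and S1pr3, a receptor for sphingosine 1-phosphate (0.73, SE 0.15), followed Egr1 among the genes with higher values. The lowest p among genes with lower values belonged to Plk3, a polo-like kinase (-1.55, SE 0.25), Slc38a3, a glutamine transporter (-1.50, SE 0.28), Slitrk1 (-1.50, SE 0.30) and Zfp185 (-0.50, SE 0.11). Of the histone deacetylases, Hdac1 was at 0.27 (SE 0.14, 0.18 without control 1 and 0.18 without Tln1 vehicle 3) and Hdac2 at 0.02 (SE 0.15), a sign that turned under several settings. None of the 22180 genes was called by limma (0 higher, 0 lower), nor with the array set as a block. In all, 322 had an unadjusted p below 0.05 (173 higher, 149 lower) where chance gives 1109. With the block, which lowered the median residual SD from 0.214 to 0.123, 1620 had such a p. Arrays of the groups did not overlap for 8.37% of genes, where chance gives 20%. Of the 21 lists, 6 were called, 10 with the array set as a block (all 6 among them), 3 without control 1, 11 without Tln1 vehicle 2, and 0 with an estimated correlation or by fry.

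**Figure D2:**
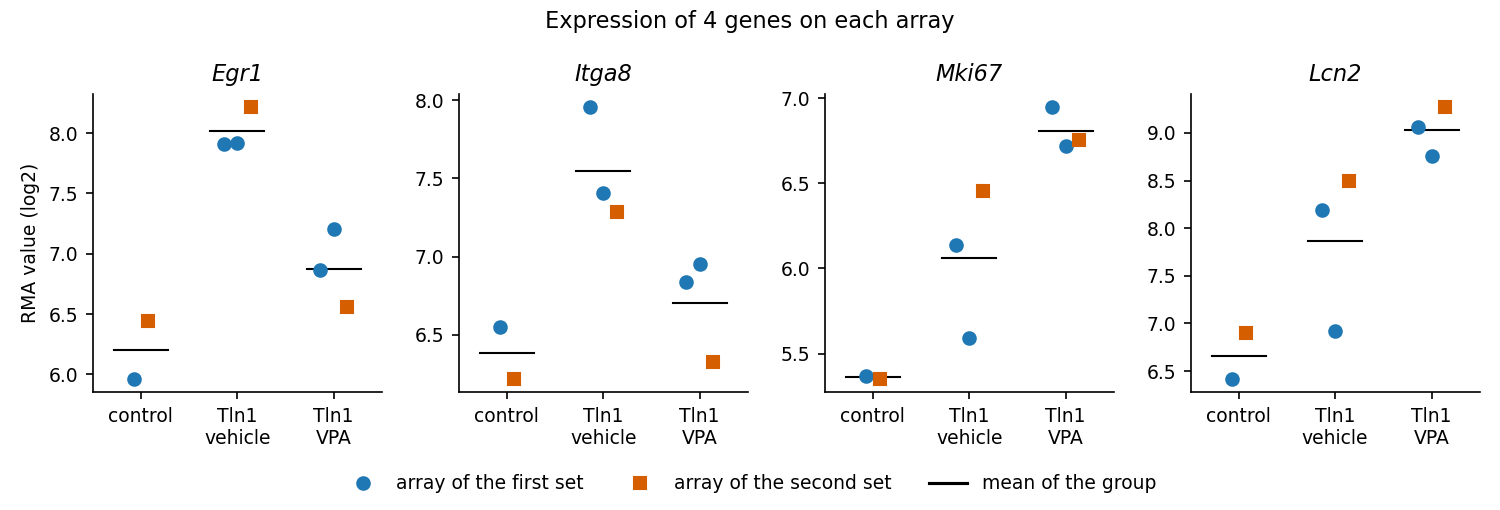
RMA value (log2) of Egr1, Itga8, Mki67 and Lcn2 on each array of the control, Tln1 vehicle and Tln1 VPA groups, with circles for the first array set, squares for the second and bars for group means. Egr1 averaged 6.20, 8.01 and 6.88 and Itga8 6.38, 7.55 and 6.71, while Mki67 (5.36, 6.06 and 6.81) and Lcn2 (6.66, 7.87 and 9.03) had their highest means in Tln1 VPA arrays.

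The second comparison, Tln1 VPA (n = 3) against Tln1 vehicle (n = 3), addressed what 2 weeks of valproic acid changed. Cell cycle genes rose most clearly: all 25 measured members were higher, and the mean level went from 4.90 ± 0.13 to 5.42 ± 0.35, with every Tln1 VPA array above every Tln1 vehicle array. Genes of NF-kB signalling and cytokines, kidney injury genes and parietal epithelial markers also rose, and mesangial and smooth muscle markers fell. None of these lists was called with an estimated correlation (smallest adjusted p = 0.0602). Egr1 again had the smallest p, at a change of -1.14 (SE 0.20), with -0.88 in the first set and -1.65 in the second.

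Cell cycle genes had the smallest p of all lists (mean 0.52, 0.64 in the first set and 0.30 in the second, adjusted p = 7.77e-28, adjusted p = 0.0602 with an estimated correlation, 6.57e-29 to 0.265 over 18 alternatives). Top2a, the DNA topoisomerase of dividing cells, was at 1.05 (SE 0.25) and Mki67 at 0.75 (SE 0.21). None passed over all genes and 0 passed adjusted over the list alone, against 14 with the array set as a block. NF-kB and cytokine genes (mean 0.30, sets 0.34 and 0.22, 24 of 26 higher, adjusted p = 4.96e-14, adjusted p = 0.0602 with an estimated correlation, 1.47e-16 to 0.265 over the alternatives) rose with them. Tnfrsf12a, the receptor for the cytokine TWEAK (1.01, SE 0.21), alone passed adjusted over the list alone, and the chemokine Ccl20 was at 0.39 (SE 0.12). Kidney injury genes (mean 0.37, 17 of 21 higher, adjusted p = 8.19e-09, adjusted p = 0.0939 with an estimated correlation, 1.59e-12 to 0.324 over the alternatives) rose as well. They included Vcam1, an adhesion molecule (1.02, SE 0.27), and Clu, clusterin (0.80, SE 0.27), with a mean of 0.51 in the first set and 0.07 in the second. Parietal epithelial markers (mean 0.31, sets 0.37 and 0.21, 9 of 10 higher, adjusted p = 3.03e-06, adjusted p = 0.0602 with an estimated correlation, 1.21e-06 to 0.265 over the alternatives) rose. Among them were Ncam1 (0.52, SE 0.20) and Dcdc2a (0.35, SE 0.16, 0.22 without Tln1 vehicle 2). Mesangial and smooth muscle markers (mean -0.26, sets -0.19 and -0.41, 15 of 17 lower, adjusted p = 1.58e-06, adjusted p = 0.0602 with an estimated correlation, 3.55e-09 to 0.265 over the alternatives) fell. Those lower included Itga8 (-0.84, SE 0.23) and Sfrp2, a secreted Wnt antagonist (-0.82, SE 0.33). These 5 calls held without any single array, though the mean of the cell cycle genes was 0.35 without Tln1 VPA 1 and that of the kidney injury genes 0.23 without Tln1 vehicle 2.

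Macrophage and myeloid markers rose (mean 0.49, 19 of 22 higher, adjusted p = 1.14e-09, adjusted p = 0.229 with an estimated correlation, 2.53e-19 to 0.562 over the alternatives). Interferon response genes rose too (mean 0.42, 18 of 20 higher, adjusted p = 5.98e-11, adjusted p = 0.174 with an estimated correlation, 2.79e-18 to 0.457 over the alternatives). Their means were 0.40 and 0.19 in the first set, where both were also called when it was tested alone, and 0.67 and 0.90 in the second. Both calls were lost without Tln1 VPA 3 (0.17 and 0.12), which leaves Tln1 vehicle 3 as the only second-set array of the 2 groups, and macrophage markers were 0.63 (SE 0.20) higher in the second set than in the first. Cd68, a lysosomal glycoprotein of macrophages, was at 0.65 (SE 0.18), H2-Ab1, an MHC class II chain, at 1.70 (SE 0.71, 0.85 without Tln1 VPA 3), Stat2 at 0.37 (SE 0.12) and Ifit1 at 0.67 (SE 0.25, 0.42 without Tln1 VPA 3). Extracellular matrix and fibrosis genes rose (mean 0.19, sets 0.20 and 0.16, 24 of 34 higher, adjusted p = 7.12e-05, adjusted p = 0.0602 with an estimated correlation, 4.01e-06 to 0.324 over the alternatives). Fibronectin, Fn1, was at 0.86 (SE 0.24) and the crosslinking enzyme Loxl1 at 0.64 (SE 0.21, 0.39 without Tln1 vehicle 3). This call was lost without Tln1 vehicle 2 (0.11), without Tln1 VPA 3 (0.16) and with the Y-linked covariate (0.16).

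Podocyte markers fell (mean -0.21, 29 of 33 lower, adjusted p = 1.53e-04, adjusted p = 0.649 with an estimated correlation, 2.50e-11 to 0.908 over the alternatives). Their mean was -0.19 in the first set and -0.24 in the second, and the call was lost without Tln1 vehicle 3 (0.04) and without Tln1 VPA 1 (-0.02). Without Tln1 vehicle 2 and without Tln1 VPA 3 their mean was -0.39 and -0.45. Synpo, the actin-associated synaptopodin, was at -0.32 (SE 0.25, -0.13 without Tln1 vehicle 3 and -0.15 without Tln1 VPA 1) and Col4a4, a collagen chain of the glomerular basement membrane, at -0.17 (SE 0.13, -0.09 without Tln1 vehicle 2 and -0.10 without Tln1 VPA 1). Endothelial markers fell (mean -0.19, sets -0.04 and -0.48, 24 of 28 lower, adjusted p = 8.87e-07, adjusted p = 0.483 with an estimated correlation, 7.02e-22 to 0.883 over the alternatives). Ehd3 was at -0.95 (SE 0.25) and Kdr at -0.65 (SE 0.28). Endothelial markers lost their call without Tln1 vehicle 3 (0.04) and in the first set alone (-0.04), and lay at -0.40 without Tln1 vehicle 2. Immediate early genes fell (mean -0.16, sets -0.00 and -0.47, 15 of 24 lower, adjusted p = 0.0134, adjusted p = 0.649 with an estimated correlation, 5.82e-07 to 0.909 over the alternatives). Fosb was at -1.13 (SE 0.36, -0.69 without Tln1 vehicle 3), and Egr1 alone passed adjusted over the list alone. That call was lost without Tln1 vehicle 3 (0.11), Tln1 VPA 1 (-0.09) or Tln1 VPA 2 (-0.11), in the first set alone (-0.00) and with the array set as a block. The mean was -0.25, -0.34 and -0.28 without Tln1 vehicle 1, Tln1 vehicle 2 and Tln1 VPA 3. Proximal tubule markers fell in the mean but were higher in the second set (mean -0.19, sets -0.34 and 0.09, 22 of 27 lower, adjusted p = 0.0452, adjusted p = 0.786 with an estimated correlation, 8.20e-11 to 0.944 over the alternatives). Napsa was at -0.29 (SE 0.27, -0.11 without Tln1 vehicle 2, -0.46 without Tln1 VPA 2 and -0.05 without Tln1 VPA 3) and the water channel Aqp1 at -0.13 (SE 0.13, -0.06 without Tln1 vehicle 2, -0.21 without Tln1 vehicle 3 and -0.05 without Tln1 VPA 3). They lay at 0.05, 0.11 and 0.21, not called, without Tln1 vehicle 1, Tln1 vehicle 2 and Tln1 VPA 3, and at -0.73, -0.35 and -0.44 without Tln1 vehicle 3, Tln1 VPA 1 and Tln1 VPA 2. Leaving out control 1 or control 2 also lost the call (-0.19), and these arrays enter only through the shared spread. Genes of fatty acid oxidation and PPARA targets rose (mean 0.24, sets 0.18 and 0.36, 17 of 22 higher, adjusted p = 1.53e-04, adjusted p = 0.575 with an estimated correlation, 2.83e-09 to 0.998 over the alternatives). Angptl4, an inhibitor of lipoprotein lipase, was at 0.98 (SE 0.25) and the pyruvate dehydrogenase kinase Pdk4 at 0.71 (SE 0.27, 0.41 without Tln1 vehicle 2). They were not called without Tln1 vehicle 3 (0.01), without Tln1 VPA 1 (0.12) or in the first set alone (0.18), and their mean was 0.43 without Tln1 vehicle 1 and 0.41 without Tln1 VPA 3.

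Among single genes, Misp, a mitotic spindle protein (0.79, SE 0.15), Tnfrsf12a and Depp1 (1.45, SE 0.33) had the smallest p values among genes with higher values. S1pr3 (-0.64, SE 0.13), the chemokine receptor-like gene Ccrl2 (-1.0, SE 0.22) and Cyp26b1, an enzyme that breaks down retinoic acid (-0.88, SE 0.21), followed Egr1 among those with lower values. Hdac1 was at 0.05 (SE 0.12), Hdac2 at 0.01 (SE 0.13) and Tln1 at -0.09 (SE 0.15), all within 1 SE of 0. limma called 0 genes higher and 0 lower, with and without the array set as a block and with the replicate number as a block. In all, 280 genes had an unadjusted p below 0.05 (185 higher, 95 lower, 1109 by chance), or 1205 with the array set as a block. Arrays did not overlap for 3.55% of genes, where chance gives 10%. Of 21 lists, 13 were called, 12 of them also with the array set as a block, and 0 with an estimated correlation or by fry.

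**Figure D3:**
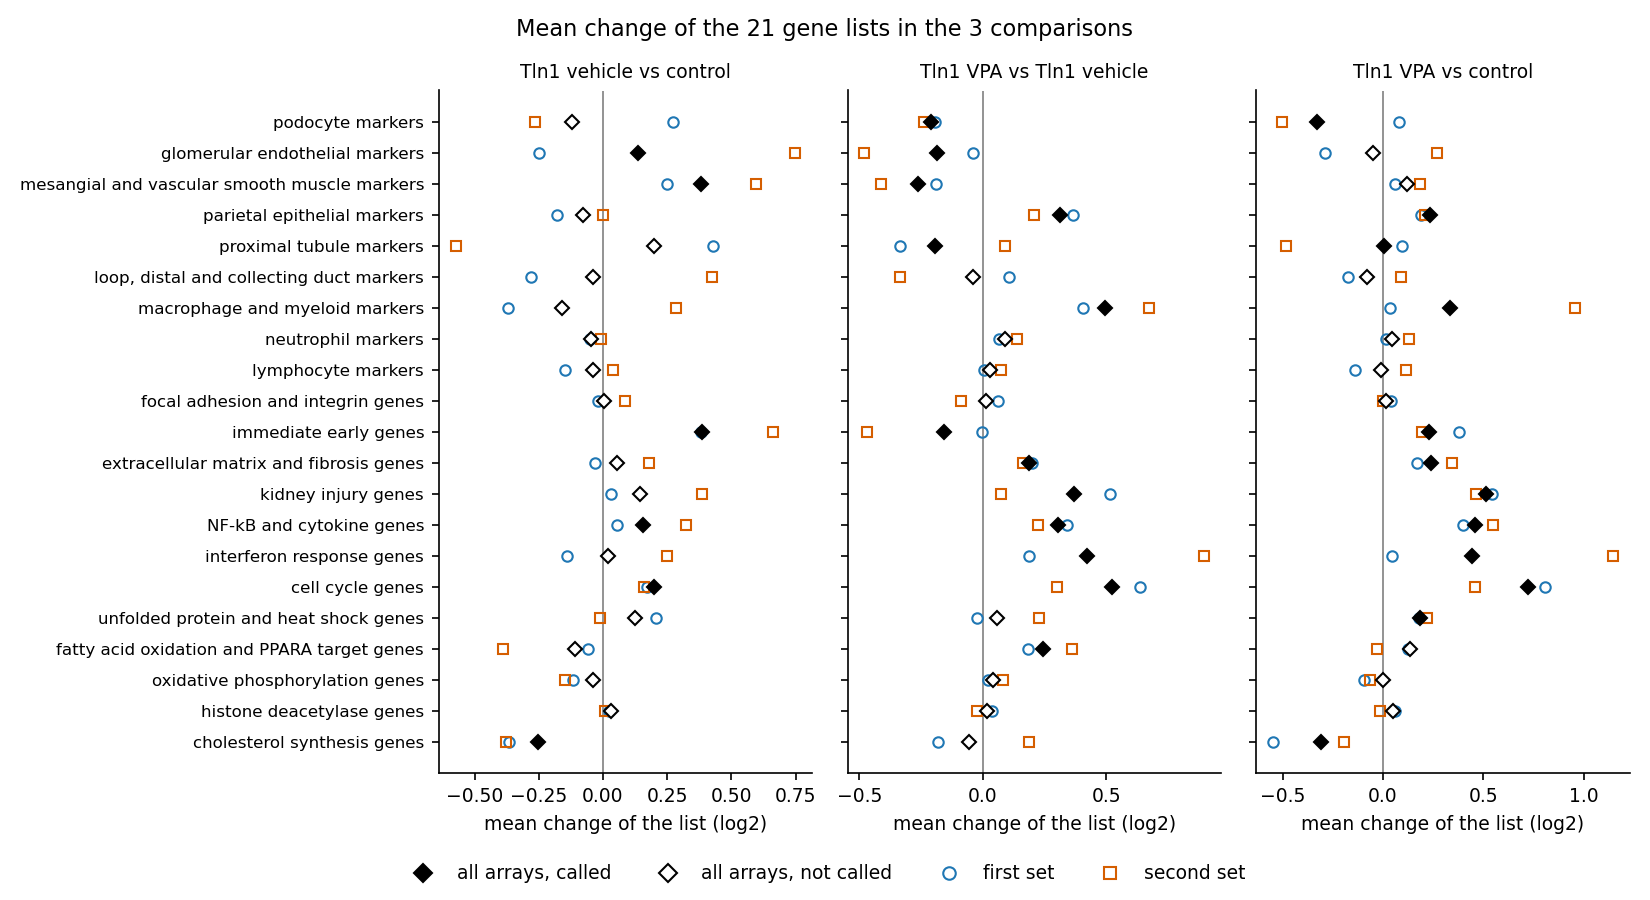
Mean log2 change (horizontal axis) of the 21 gene lists (vertical axis) in the 3 comparisons, with diamonds for all arrays, filled where camera with the preset correlation called the list, circles for the first array set and squares for the second. Cell cycle genes lie right of 0 in both sets of each comparison (0.17 and 0.16, 0.64 and 0.30, 0.81 and 0.46), while podocyte markers against control lie on both sides (0.27 and -0.26 in Tln1 vehicle, 0.08 and -0.50 in Tln1 VPA arrays).

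The third comparison, Tln1 VPA (n = 3) against control (n = 2), gave the distance from control after treatment. Lcn2, the tubular injury protein lipocalin 2, averaged 6.66 ± 0.34 in control, 7.87 ± 0.83 in Tln1 vehicle and 9.03 ± 0.26 in Tln1 VPA arrays, a change of 2.37 (SE 0.44) with 2.49 in the first and 2.37 in the second set. Mki67 was at 1.45 (SE 0.24), with 1.46 and 1.40 in the sets. The cell cycle, NF-kB and cytokine, and kidney injury lists rose, with every Tln1 VPA array above both control arrays and calls that held without any single array. None of the 3 was called with an estimated correlation (adjusted p = 0.148, 0.114 and 0.172). Egr1 was at 0.67 (SE 0.23, 0.43 without control 1), with 1.07 in the first set and 0.12 in the second.

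Of 25 cell cycle genes, 24 were higher (mean 0.72, sets 0.81 and 0.46, adjusted p = 4.13e-28, adjusted p = 0.148 with an estimated correlation, 7.19e-29 to 0.234 over 18 alternatives). Prc1, a protein of the central spindle, was at 1.26 (SE 0.27). None passed over all genes and 7 passed adjusted over the list alone. Of 26 NF-kB and cytokine genes, 25 were higher (mean 0.46, sets 0.40 and 0.55, adjusted p = 5.43e-17, adjusted p = 0.114 with an estimated correlation, 2.63e-21 to 0.234 over the alternatives). Tnfrsf12a was at 1.43 (SE 0.24) and alone passed adjusted over the list alone, and Birc3, an inhibitor of apoptosis, was at 0.44 (SE 0.12). Of 21 kidney injury genes, 18 were higher (mean 0.51, sets 0.54 and 0.46, adjusted p = 8.20e-08, adjusted p = 0.172 with an estimated correlation, 1.37e-11 to 0.377 over the alternatives). Clu was at 1.09 (SE 0.30, 0.70 without control 2), and Lcn2 alone passed adjusted over the list alone.

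Other calls against control were lost when 1 array was left out or in 1 array set. Podocyte markers fell (mean -0.33, 30 of 33 lower, adjusted p = 1.68e-06, adjusted p = 0.564 with an estimated correlation, 1.15e-24 to 0.976 over the alternatives). Sema3g was at -1.49 (SE 0.43, -0.94 without control 2) and Synpo at -0.50 (SE 0.28, -0.82 without control 1, -0.18 without control 2 and -0.33 without Tln1 VPA 1). The list was called higher without control 2 (0.31), lost its call without Tln1 VPA 1 (-0.14) and with the Y-linked covariate (-0.03), and averaged 0.08 in the first set and -0.50 in the second. Its mean was -0.97 without control 1 and -0.57 without Tln1 VPA 3. Cholesterol synthesis genes fell (mean -0.31, sets -0.55 and -0.19, 15 of 16 lower, adjusted p = 3.54e-07, adjusted p = 0.415 with an estimated correlation, 3.53e-10 to 0.840 over the alternatives). Fdps was at -0.55 (SE 0.21, -0.16 without control 1 and -0.94 without control 2) and Dhcr7 at -0.45 (SE 0.19, -0.19 without control 1 and -0.72 without control 2), and without control 1 the list was not called (0.05). Its mean was -0.67 without control 2 and -0.19 without Tln1 VPA 3. Interferon response genes rose (mean 0.44, 19 of 20 higher, adjusted p = 8.20e-08, adjusted p = 0.344 with an estimated correlation, 3.06e-15 to 0.555 over the alternatives), with Stat2 at 0.45 (SE 0.14) and Oasl2 at 0.65 (SE 0.25, 0.42 without control 2). Macrophage and myeloid markers also rose (mean 0.33, 20 of 22 higher, adjusted p = 0.00112, adjusted p = 0.564 with an estimated correlation, 1.55e-15 to 0.843 over the alternatives). Cd68 was at 0.63 (SE 0.20) and Cd14 at 0.44 (SE 0.24, 0.22 without Tln1 VPA 1). In the first set these lists averaged 0.05 and 0.04, against 1.15 and 0.96 in the second, and without Tln1 VPA 3 both calls were lost (0.14 and 0.01), as was that of the macrophage markers without control 1 (0.30), which averaged 0.58 without Tln1 VPA 2.

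Extracellular matrix and fibrosis genes rose (mean 0.24, sets 0.17 and 0.34, 25 of 34 higher, adjusted p = 6.16e-04, adjusted p = 0.151 with an estimated correlation, 6.68e-07 to 0.273 over the alternatives). The protease inhibitor Timp1 was at 0.53 (SE 0.15) and S100a6 at 1.00 (SE 0.32). Matrix genes lost their call without control 1 (0.28), without Tln1 VPA 3 (0.21) and in the first set alone (0.17). Parietal epithelial markers rose (mean 0.24, sets 0.19 and 0.21, 8 of 10 higher, adjusted p = 0.00750, adjusted p = 0.306 with an estimated correlation, 0.00195 to 0.555 over the alternatives). Cd44 was at 0.46 (SE 0.25, 0.29 without Tln1 VPA 3) and Dcdc2a at 0.44 (SE 0.18, 0.28 without control 1). Parietal markers were not called without control 1 (0.36), control 2 (0.11) or Tln1 VPA 1 (0.16), nor among genes above the median level (0.21). Immediate early genes rose (mean 0.23, sets 0.38 and 0.19, 18 of 24 higher, adjusted p = 0.0134, adjusted p = 0.757 with an estimated correlation, 1.33e-11 to 0.930 over the alternatives), with Ccn1 at 1.20 (SE 0.61, 0.78 without control 1 and 0.78 without Tln1 VPA 3). Without control 1 (-0.04) and without Tln1 VPA 3 (0.11) they were not called, and they lay at 0.50 without control 2. Genes of the unfolded protein and heat shock responses rose (mean 0.18, sets 0.18 and 0.22, 21 of 23 higher, adjusted p = 0.00449, adjusted p = 0.363 with an estimated correlation, 3.27e-04 to 0.555 over the alternatives). The chaperones Hspa1b and Hspa5 were at 0.89 (SE 0.54, 0.48 without control 1 and 0.42 without Tln1 VPA 3) and 0.24 (SE 0.16, 0.06 without control 1 and 0.41 without control 2), and the call was lost without control 1 (0.16) and without Tln1 VPA 3 (0.15). Proximal tubule markers were called lower (sets 0.09 and -0.48, 19 of 27 lower, adjusted p = 0.00248, adjusted p = 0.787 with an estimated correlation, 3.42e-14 to 0.946 over the alternatives). Hao2 was at -0.96 (SE 0.24) and Aqp1 at -0.44 (SE 0.14). Their mean (0.01) and median (-0.16) differed in sign, and the call was lost without control 1 (0.32) and without Tln1 VPA 3 (0.40). The mean was -0.30, -0.15 and -0.24 without control 2, Tln1 VPA 1 and Tln1 VPA 2.

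Among single genes, Adamts1 was at 0.88 (SE 0.13), Cyp4a12b at 1.35 (SE 0.23), Slc38a3 at -1.72 (SE 0.28), Slitrk1 at -1.71 (SE 0.30) and Zfp185 at -0.49 (SE 0.11). These genes are also named above for Tln1 vehicle against control, which uses the same 2 control arrays, so the 2 sets of values are not independent. Bhmt, an enzyme of methionine metabolism, was at -1.40 (SE 0.28). Hdac1 was at 0.32 (SE 0.14), Hdac2 at 0.03 (SE 0.15) and Tln1 at -0.06 (SE 0.17). limma called 0 genes higher and 0 lower, and none with the array set as a block. In all, 414 genes had an unadjusted p below 0.05 (272 higher, 142 lower, 1109 by chance), or 1800 with the block. With the Y-linked mean as a covariate 6 genes were called higher, among them Lcn2 (2.70), Ccn1 (1.78) and Mki67 (1.59), and 15 lower, among them Slc38a3 (-1.93). With the array set added as a block, Ccn1 (1.67) and Dnase1 (-1.42), the last chosen after its values were seen, remained called. Arrays did not overlap for 9.55% of genes, where chance gives 20%. Of 21 lists, 12 were called, all 12 also with the array set as a block, 5 without control 1, and 0 with an estimated correlation or by fry.

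In all, 6 lists were called in no comparison. Histone deacetylase and sirtuin genes averaged 0.03, 0.02 and 0.05 in the 3 comparisons in the order above (adjusted p = 0.768, 0.720 and 0.569), focal adhesion and integrin genes 0.00, 0.01 and 0.02 (adjusted p = 0.808, 0.720 and 0.969), and oxidative phosphorylation genes -0.04, 0.04 and 0.00 (adjusted p = 0.237, 0.513 and 0.487). Neutrophil markers averaged -0.05, 0.09 and 0.04 (adjusted p = 0.344, 0.0817 and 0.742), lymphocyte markers -0.04, 0.03 and -0.01 (adjusted p = 0.457, 0.539 and 0.779), and markers of the loop of Henle, distal tubule and collecting duct -0.04, -0.04 and -0.08 (adjusted p = 0.808, 0.134 and 0.201). The means of these loop and distal markers average opposite shifts in the array sets (sets -0.28 and 0.42, 0.11 and -0.34, and -0.18 and 0.09). Lymphocyte markers against control also had opposite signs in the sets (-0.15 and 0.04 in Tln1 vehicle, -0.14 and 0.11 in Tln1 VPA arrays). The mean log2 level per array was 3.28 to 3.55 for neutrophil markers and 3.70 to 3.96 for lymphocyte markers. These levels lie below the median gene mean, so small changes in these lists cannot show whether such cells changed. With the array set as a block, oxidative phosphorylation genes were called lower against control in Tln1 vehicle (-0.13) and Tln1 VPA arrays (-0.09), but not with the block and an estimated correlation (adjusted p = 0.433 and 0.311). Loop and distal markers against control and lymphocyte markers in Tln1 VPA arrays against control had medians of the opposite sign (0.03, 0.05 and 0.03), as had histone deacetylase genes against control (-0.00 and -0.01). Focal adhesion genes in Tln1 vehicle arrays were tested as lower with a median of 0.02.

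Other lists were not called in single comparisons. In Tln1 vehicle against control these were proximal tubule markers (mean 0.20, median -0.12, tested as lower, adjusted p = 0.164), macrophage and myeloid markers (-0.16, adjusted p = 0.112), parietal epithelial markers (mean -0.08, median 0.09, adjusted p = 0.457) and kidney injury genes (0.15, adjusted p = 0.344). Unfolded protein and heat shock genes (0.12, adjusted p = 0.164), fatty acid oxidation genes (mean -0.11, median 0.06, adjusted p = 0.457), matrix genes (0.05, adjusted p = 0.808) and interferon response genes (0.02, adjusted p = 0.912) were also not called there. Macrophage markers (sets -0.37 and 0.28), interferon response genes (-0.14 and 0.25), matrix genes (-0.03 and 0.18) and unfolded protein genes (0.20 and -0.01) had opposite signs in the sets. With the array set as a block, proximal tubule markers were called lower (median -0.26, mean -0.00, with means of 0.43 in the first set and -0.57 in the second). Kidney injury (0.17) and unfolded protein genes (0.12) were called higher with the block. None of these 3 was called with the block and an estimated correlation (adjusted p = 0.780, 0.834 and 0.780). In Tln1 VPA against Tln1 vehicle, unfolded protein genes (0.06, sets -0.03 and 0.23, adjusted p = 0.132) and cholesterol synthesis genes (-0.06, sets -0.18 and 0.19, adjusted p = 0.273) were not called. In Tln1 VPA against control, mesangial and smooth muscle markers (0.12, adjusted p = 0.219), endothelial markers (-0.05, sets -0.29 and 0.27, adjusted p = 0.239) and fatty acid oxidation genes (0.13, sets 0.13 and -0.03, adjusted p = 0.0590) were not called. Of the 17824 probe sets with several symbols or none, 0 were called in any comparison, and 557, 395 and 511 had an unadjusted p below 0.05.

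Whether valproic acid moved genes back toward control was examined across genes, which are not independent replicates. The changes in Tln1 vehicle against control and in Tln1 VPA against Tln1 vehicle correlated at r = -0.360 over 22180 genes, where groups without any change that share the vehicle arrays gave -0.397 (-0.423 to -0.365 over 100 simulations) and groups without a drug effect -0.263 (-0.305 to -0.230). The covariance was -0.0122, against -0.00789 without any change (a difference of -0.00434) and -0.00785 (-0.00912 to -0.00684) without a drug effect. The simulations drew the noise of each gene independently, while genes of real arrays move together. Their ranges, also that of the share below, are therefore too narrow, and a value outside them is no evidence of a move back. The simulation without a drug effect also took the difference between control and Tln1 arrays from these same arrays, noise included. Its correlation may therefore be too weak and its share too low. Without Tln1 vehicle 3 the correlation was -0.721 and without Tln1 VPA 3 it was -0.107. Swapping which of the 6 Tln1 arrays stood for vehicle and which for valproic acid gave -0.234 to -0.756. Among swaps that parted all same-numbered pairs it was -0.254 to -0.428. Both ranges are wider than the simulated ones. Of the 67 genes with an unadjusted p below 0.01 in the first comparison, 51 (76.1%) had the opposite sign in the second, against 71.9% (64.8 to 80.7) without a drug effect and 88.5% (69.2 to 100) without any change. The 3 vehicle arrays cannot be split into 2 parts of 2, so part of these values may come from the shared arrays. Egr1, Itga8, S1pr3 and Ehd3 were among the named genes with higher values in every Tln1 vehicle array than in any control or Tln1 VPA array, and none of them passed over all genes. Apart from Egr1, they were named for a small p in comparisons that share these vehicle arrays. That rule favours such genes, so they are no support for a move back.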

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

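The array set as a block, the first set alone, the Y-linked covariate and their combination were added after the data had been seen. In the order Tln1 vehicle against control, Tln1 VPA against Tln1 vehicle and Tln1 VPA against control, 6, 13 and 12 gene lists were called. None was called with an estimated correlation (0, 0 and 0), by fry (0, 0 and 0), or with the array set as a block and an estimated correlation (0, 0 and 0). Of 2146 gene values from 98 results, 42 changed sign, and 89 results never did. Most of these genes were named for a small p or for arrays without overlap in these same data. Where arrays do not overlap, leaving out 1 array cannot turn the sign. Trended eBayes, the fit of only 2 groups and every probe set as its own row leave the change as it is. Steady signs were thus partly fixed in advance and are no support. Of 576 list values from 32 results, 406 kept their direction and stayed called or not called as in the main fit. Another 143 lost the call, 3 gained it and 24 turned by camera's direction. Values near 0, as for Tln1 and Hdac2, turned most often. Centring on array medians put Tln1 at -0.00657 in Tln1 vehicle against control and Hdac2 at -0.0150, -0.000560 and -0.0156 in the 3 comparisons. Quantile normalisation put Hdac2 at -0.00327, -0.0104 and -0.0137. Array weights, which ran from 0.254 (Tln1 vehicle 3) to 6.51 (Tln1 vehicle 1), put Hdac2 at -0.0107, -0.0191 and -0.0298 and Tln1 at 0.00789 in Tln1 VPA against control. The proximal tubule covariate put Tln1 at -0.0155 in Tln1 vehicle against control and Hdac2 at -0.0147 in Tln1 VPA against Tln1 vehicle, and 1 gene was called lower in Tln1 VPA against control (Slc16a4, -1.30, chosen after its values were seen). The array set as a block gave 10 lists in Tln1 vehicle against control and put Tln1 at -0.0198 and podocyte markers at 0.0267 there. The first set alone put Tln1 at -0.0182, Foxc2 at 0.000275, Enpep at 0.0977, Kdr at -0.102, podocyte markers at 0.274 and endothelial markers at -0.247 in Tln1 vehicle against control. It put Hdac2 at -0.0568 in Tln1 VPA against Tln1 vehicle and podocyte markers at 0.0788 in Tln1 VPA against control. The Y-linked covariate gave 15 lists in Tln1 vehicle against control and put Tln1 at -0.158, Foxc2 at 0.0185, Enpep at 0.00196 and podocyte markers at 0.357 there. It put Hdac2 at -0.0221 and proximal tubule markers at 0.122 in Tln1 VPA against Tln1 vehicle, gave 6 genes higher and 15 lower in Tln1 VPA against control, and moved the correlation of the changes from -0.360 to -0.573. With the block added, 1 gene was higher and 1 lower in that comparison, Tln1 lay at -0.0470 and Hdac2 at -0.0907 in Tln1 vehicle against control, and Hdac2 at -0.0165 in Tln1 VPA against control. Leaving out each array gave 3 to 11, 11 to 14 and 5 to 13 lists, 0 to 0 genes, a correlation from -0.721 to -0.107 and a share of opposite genes from 68.8% to 92.3%. Tln1 ran from -0.13 to 0.19 in Tln1 vehicle against control and from -0.22 to 0.10 in Tln1 VPA against control, Hdac1 from -0.0192 to 0.14 in Tln1 VPA against Tln1 vehicle, and Hdac2 from -0.17 to 0.21, -0.0672 to 0.0437 and -0.16 to 0.22. In Tln1 vehicle against control Foxc2 ran from -1.53 to 0.37, Enpep from -0.73 to 0.22, podocyte markers from -0.76 to 0.52, endothelial markers from -0.0909 to 0.35 and immediate early genes from 0.11 to 0.65. In Tln1 VPA against Tln1 vehicle podocyte markers ran from -0.45 to 0.0402, endothelial markers from -0.40 to 0.0415, proximal tubule markers from -0.73 to 0.21 and immediate early genes from -0.34 to 0.11. In Tln1 VPA against control podocyte markers ran from -0.97 to 0.31, macrophage markers from 0.00559 to 0.58 and immediate early genes from -0.0404 to 0.50. The cause of these shifts was not tested, and with 2 or 3 arrays per group 1 array carries much of each mean.

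With the replicate number as a block, 4 genes were called higher in Tln1 vehicle against control (Ces1f 4.01, Ces1g 3.74, Cyp2e1 2.23 and Cyp2j13 6.87) and 1 in Tln1 VPA against control (Ces1g 4.06), all chosen after their values were seen. Lists called were 8, 13 and 11, but only 2 of the 6 calls in Tln1 vehicle against control held, those of mesangial (0.34) and cell cycle genes (0.32). Immediate early (0.19), NF-kB (0.10), cholesterol (-0.07) and endothelial genes lost theirs, and podocyte markers were called lower (-0.36). Matrix genes (0.20) and the 3 lists that turned, proximal tubule, macrophage and immediate early, lost their calls in Tln1 VPA against control. The correlation was -0.293 and the share of opposite genes 75.4%. Hdac2 lay at -0.0209 and endothelial markers at -0.0176 in Tln1 vehicle against control. In Tln1 VPA against control Tln1 lay at 0.0326, Hdac2 at -0.0145, proximal tubule markers at 0.475, macrophage markers at 0.0506 and immediate early genes at 0.0333. In both comparisons with control, replicate 2 holds arrays of both sets. Sex-linked genes averaged 6.74 and 7.09 in Tln1 vehicle 1 and 2, 6.17 and 6.86 in Tln1 VPA 1 and 2, and 5.11 and 4.69 in control 1 and 2. A different mix of male and female RNA may therefore enter the genes called with this block, which was not tested. In Tln1 VPA against Tln1 vehicle, whose arrays were taken as paired, the block changed no call.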

Other observations

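Lcn2, the lipocalin that injured tubules release, averaged 6.66 in control, 7.87 in Tln1 vehicle and 9.03 in Tln1 VPA arrays, and Mki67 5.36, 6.06 and 6.81. Mesangial and smooth muscle markers went the other way under valproic acid, from 7.11 in Tln1 vehicle to 6.84 in Tln1 VPA arrays, with control at 6.72. Their rise and their fall share the same Tln1 vehicle arrays. A list that is high in these arrays tends to fall against them without a drug effect, so this is no support for a move back. Lcn2 and Mki67 passed over all genes only in Tln1 VPA against control with the Y-linked covariate (limma adjusted p = 0.0357 and 0.0473), and the mesangial list was not called with an estimated correlation.

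The tests on Egr1 were chosen after its values were seen. With the array set and the Y-linked covariate its change from control to Tln1 vehicle was 1.63 (SE 0.41, 95% interval 0.33 to 2.93). This cannot exclude a mix of male and female RNA, since the Y-linked signal moved with the Tln1 groups in the first set. Egr1 also had the smallest p of all genes here, so an interval above 0 was likely from the start. With only the set as a block the change was 1.82 (SE 0.28, 95% interval 1.04 to 2.60), against 1.81 without it. The array sets therefore do not account for all of the higher value in these arrays. Since Egr1 was tested for its small p, this interval too was likely to lie above 0. An immediate early response of the tissue, including to handling during isolation, may be the source, but the values for it depend on the block: with the set as a block 20 of the 23 other immediate early genes were higher (median 0.23), while without it 18 of all 24, Egr1 included, were higher, and the list mean was 0.12 without control 1 and 0.11 without Tln1 vehicle 3. Handling times are not given in the sources used here, and this explanation stays open.

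The tests on the cell cycle and NF-kB genes in Tln1 VPA against Tln1 vehicle arrays were also chosen after the result was seen. More leukocytes in the isolate might raise both lists. With the array set as a block and the macrophage marker mean as a covariate the cell cycle change was 0.56 (SE 0.24, 95% interval -0.22 to 1.33) against 0.52 without it, and the NF-kB change 0.17 (SE 0.11, 95% interval -0.17 to 0.50) against 0.30. A different share of glomerular cells could also matter, and parietal markers minus proximal tubule markers changed by 0.51 (SE 0.30, 95% interval -0.32 to 1.34). All 3 intervals include 0, so both explanations stay open.

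The tests on the array sets were chosen after the sets were seen. Processing in 2 runs may explain them, since the sorted values of arrays differed by at least 0.104 across the sets and by at most 0.0409 within a set, though RMA equalises probes and not probe sets, so a difference in tissue could leave such a gap too. Different shares of tubule and glomerular RNA may add to them, since the second set differed from the first by -1.19 (SE 0.21) in proximal tubule markers and by 0.88 (SE 0.16) in podocyte markers. Between the sets 10950 genes differed. The sets were formed by clustering these same values, so many differing genes and small standard errors were built in and are no support for either explanation. The 2 explanations may both hold.

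Regrouping of the 6 Tln1 arrays was fixed beforehand for the counts and chosen afterwards for the correlation and the share, and the 10 splits into 3 and 3 are too few for a share under 0.05. For genes called higher the real split gave 0 and the highest other 0, so 10 of 10 reached it, and for genes called lower 10 of 10 as well. For lists, 4 of 10 splits reached the real 13 (highest other 16), and among splits that part all 3 same-numbered pairs the highest other gave 12. Over 20 assignments of roles, 13 reached the real correlation of -0.360 (most negative other -0.756, or -0.428 among those parting all pairs), and 16 reached the real share of 76.1% (highest other 91.4%, or 90.2%). Splits with uneven array sets, which compare the sets themselves, had up to 2751 genes with an unadjusted p below 0.05, and among the 6 splits with even sets, a choice made afterwards and too few for a share under 0.05, the real one had the most such genes (280, highest other 158) and lists (13, highest other 12).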
